A study of Mus musculus with 12 samples.

How the data were processed

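RNA was profiled by sequencing in mesenchymal cells sorted by flow cytometry from the uteri of healthy cycling Pdgfrb-BAC-eGFP mice, which carry a green fluorescent protein reporter for Pdgfrb on a bacterial artificial chromosome. The libraries fall into 2 groups of 6, named per the labels as GFPtotal (all GFP-positive cells, that is GFP-high perivascular cells plus GFP-low stromal fibroblasts) and GFPlow (the GFP-low cells alone). The series describes 12 mice for 12 libraries, and no label ties a replicate number of one group to a mouse of the other. No label ties a library to a single mouse either, so the p-values measure the spread between these libraries. Per the labels, the libraries carry the name of a TruSeq DNA Nano gel-free preparation and were run on 4 lanes of an Illumina HiSeq 4000.

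The deposited values are raw read counts per gene. Per the file headers, the authors counted paired-end fragments over exons with featureCounts 1.6.4, summed them by gene of Ensembl release 84 on GRCm38, required a mapping quality of at least 10 and did not use strand. Per the submitters' processing notes, cutadapt and SAMtools were used and the build was GRCm38. The aligner is not given in the sources used here. A deposited table of the whole series held the same counts as the single files in 12 of 12 libraries and had 0 columns without a sample. The files list 47729 genes. Gene symbols were found by Ensembl identifier for 47224 of them in a GENCODE M21 table, and coordinates are those of the files. The 120 genes that share a symbol with another identifier were not matched by symbol. No genome sequence was used here.

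Because strand was not used in the counting, reads of a gene and of an overlapping antisense gene cannot be told apart. Of 77 named genes, 23 share exonic bases with another gene, and 3 share 10% or more of theirs: Itgam (68.7%, with Gm49368), Micall1 (29.7%, antisense) and Alas2 (15.5%, antisense). Genes with near-identical copies or related genes may have lost or exchanged reads at the mapping step and are uncertain to that extent. Among them are the Ifit family, Acta2 and Actg2, class I antigen genes, Hspa1a and Hspa1b, and mitochondrially encoded genes with nuclear copies. Olfr78 and Olfr558 are related genes rather than near-identical copies. The similarity of these sequences and any exchange of reads were not tested.

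Total counts ranged from 12631266 to 18425596 per library. The 2 mitochondrial ribosomal RNAs took 26.4% to 38.6% of them and all mitochondrial genes 32.4% to 49.0%, which left 6978218 to 10834905 nuclear counts. Libraries of one group were compared with each other before averaging. Their Spearman correlations were 0.851 to 0.937 in GFPtotal and 0.873 to 0.934 in GFPlow, and the chi-square per degree of freedom of a pair was at least 21.3 and 27.5, so no pair agreed within sampling noise.

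From the counts, genes were kept by edgeR's filterByExpr, scaled by trimmed mean of M-values (TMM) factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust dispersion estimates), GFPtotal minus GFPlow, with no covariate. This left 14523 genes. P-values are two-sided and were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM are edgeR's depth-normalised counts on TMM-scaled library sizes, given as mean ± SD, and log2 CPM used a prior count of 2. An exact two-sided permutation test over the 924 assignments of 6 labels to 12 libraries was used for Pdgfrb and for summed markers. Intervals of a ratio of counts are exact 95% binomial intervals and cover counting error only.

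Before the data were examined, 21 gene lists were fixed: markers of pericytes, smooth muscle, fibroblasts, epithelium, endothelium, leukocytes, mesothelium, Schwann cells and glia, and erythroid cells, and genes of uterine stromal identity, decidualization, fibrillar matrix, basement membrane, Notch, TGF-beta and BMP, angiogenic factors, ion channels and contractile signalling, cell cycle, immediate early response, interferon response and class I antigen presentation, and mitochondrially encoded proteins. Lists of at least 3 tested genes (19 lists) were tested on log2 CPM with camera (limma 3.58.1) at a preset correlation of 0.01 between genes. The same test with an estimated correlation and fry were alternatives. Some genes stand in more than 1 list (8 of the 20 pericyte markers do).

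Genes named in the text were chosen by a rule fixed in advance. It takes Pdgfrb, up to 4 called genes of each list with the largest change (or the 2 most abundant where none was called), the 10 largest changes in each direction among called genes of mean log2 CPM of at least 3 whose groups did not overlap, and the 5 smallest p-values in each direction. Predicted genes and symbols without a name were left out. Protein-coding genes within 200 kb of Pdgfrb were also taken, because the reporter is carried on a large genomic clone. Other members of the fixed lists are given as examples of their list. The values of a few genes that the rule or the lists take are not reported here.

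The alternatives fixed in advance were relative log expression (RLE) and upper-quartile factors, total library size alone, no low-count filter, a stricter one (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom with quality weights, a replicate block, the other list tests, and leaving out each of the 12 libraries in turn. Leaving out GFPtotal 3, 4 and 5 together and removing mitochondrial genes were chosen after seeing the data. The procedure was tested on simulated data: in 5 simulations of 14523 genes with 200 changed genes each, 16.5% of 2-fold, 63.5% of 4-fold and 85.5% of 8-fold rises were recovered, and 13.3%, 58.8% and 72.1% of falls of those sizes. Of the simulated calls, 4.28% were false. The changed gene set was called in 5 of 5 simulations and 0 of 95 unchanged sets were. Simulated genes were drawn independently of each other, so the set result does not cover lists whose genes vary together. In the data, estimated correlations within lists ran from −0.061 (Notch) to 0.830 (mitochondrially encoded proteins), with 0.489 for the interferon list.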

Results

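Gene expression was measured in GFPtotal and GFPlow cells of the mouse uterus, with 6 libraries per group. GFPtotal cells are a mixture of GFP-high and GFP-low cells, in proportions that are not given in the sources used here. Total counts were 12631266 to 14950639 per GFPtotal library and 14339804 to 18425596 per GFPlow library, and 18228 to 21587 genes had at least 1 count. The comparison addresses which transcripts mark the GFP-high perivascular cells, whose profile the study inferred from GFPtotal against GFPlow.

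Pericyte markers were far higher in GFPtotal than in GFPlow cells, with 12 of 14 tested members called. Part of the contractile genes (8 of 18) was also called higher, as were ion channel and contractile signalling genes (7 of 17). The same held for part of the angiogenic factors (5 of 18) and cell cycle genes (6 of 16). Rgs5, a regulator of G-protein signalling used as a pericyte marker, stood at 782 ± 114 CPM in GFPtotal and 4.80 ± 3.95 CPM in GFPlow (SD, n = 6 each; log2 fold change 7.34, SE 0.63, adjusted p = 3.84e-05). Fewer genes were lower, and by less: the hedgehog target gene Gli1, the ligand gene Wnt4 and the neuronal nitric oxide synthase gene Nos1 were among them. The fibroblast genes Dcn, Pdgfra and Lum had log2 fold changes of 0.39, 0.30 and 0.20 that did not pass the test.

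Of 14523 genes tested, 785 differed at an adjusted p below 0.05. They were 661 higher and 124 lower in GFPtotal, of which 575 and 78 differed at least 2-fold. The median log2 fold change was 2.03 among the higher genes and −1.15 among the lower ones. Higher genes made up 84.2% of the calls, and 66.3% with total library size as the only scaling, where the number of genes lower in GFPtotal was 257. The 6 libraries of one group lay wholly above the 6 of the other for 415 genes in GFPtotal and for 117 in GFPlow, where chance gives 31.4 genes (0.216% of those tested) in both directions together. GFPtotal 3, 4 and 5 stood apart on the first principal component (34.0% of the variance), at 102 to 107 against −3.82 to 6.66 for GFPtotal 1, 2 and 6 and −64.6 to −31.1 for GFPlow. Without those 3 libraries, an alternative chosen after seeing the data, the number of genes changed was 295 (genes higher in GFPtotal, 245, and genes lower in GFPtotal, 50), of which 234 were also called, in the same direction, with all libraries. Without GFPtotal 3 alone the count was 467, and without GFPtotal 4 alone 521. GFPlow 5 stood apart on the second principal component (11.4% of the variance), at −86.6. The other GFPlow libraries lay there at −22.1 to 4.45 and the GFPtotal libraries at −26.2 to 51.9. Without GFPlow 5 the count was 803. Camera called 9 of 19 gene lists, a number that 11 of 100 splits of the libraries reached, the real one included, and 5 with an estimated correlation, which the real split alone reached. The other splits that reached 9 kept 4 or 5 of the 6 libraries of a group together, and so part of the real difference.

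Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061, GRCm38), the gene whose reporter defined the sort, was higher in GFPtotal at 114.3 ± 36.02 CPM against 65.06 ± 15.02 CPM (SD, n = 6 each). Its log2 fold change was 0.81 (SE 0.21, adjusted p = 0.0305). An exact two-sided permutation test gave p = 0.00866, where the smallest possible value was 0.00216. The call on the Pdgfrb log2 fold change was lost without GFPtotal 3, 4 and 5 (0.64, adjusted p = 0.207), and without GFPtotal 4, 5 or 6 or GFPlow 1, 2, 3 or 5 alone (adjusted p = 0.0576 to 0.0789).

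**Figure D1:**
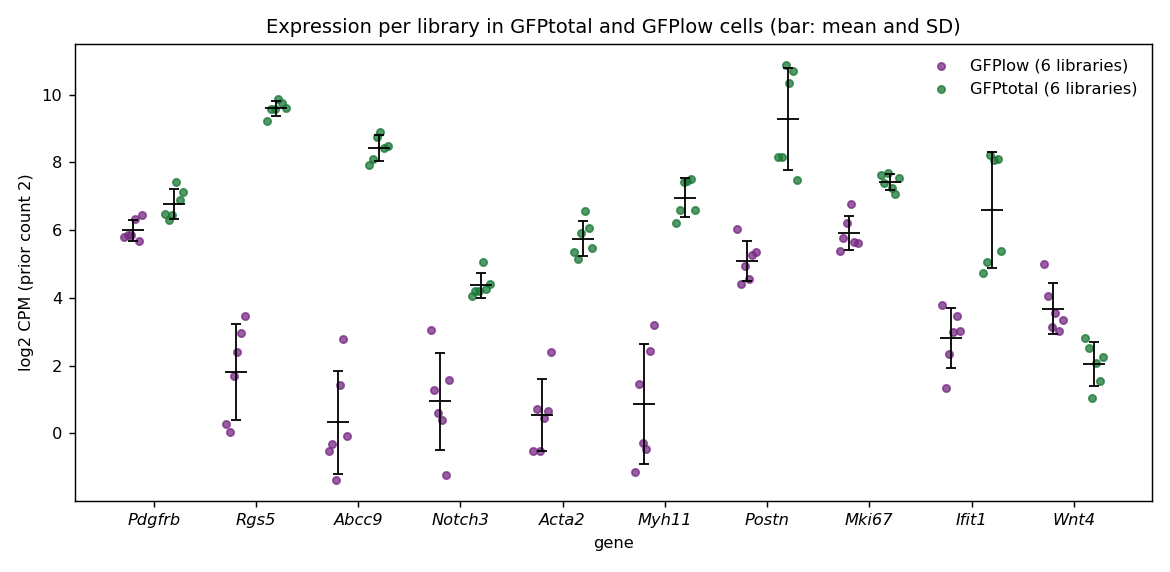
Expression of 10 named genes as log2 CPM (vertical axis) in GFPlow (purple) and GFPtotal (green) cells, with a dot per library and black bars for the mean and SD over 6 libraries. Rgs5 and Abcc9 separate the groups without overlap, Pdgfrb does not, and Postn and Ifit1 spread widely among the GFPtotal libraries.

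Pericyte markers formed the most shifted list: 12 of its 14 tested members were higher and 0 lower (13 and 0 adjusted over the list alone), with a median log2 fold change of 3.48. Abcc9 (ENSMUSG00000030249) and Kcnj8 (ENSMUSG00000030247), which lie next to each other on chromosome 6 and encode the subunits of an ATP-sensitive potassium channel, had log2 fold changes of 7.54 (SE 0.77, adjusted p = 0.000217) and 5.45 (SE 1.13, adjusted p = 0.0121). Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, and the proteoglycan gene Cspg4 followed at 4.75 and 4.05. Notch3 differed by 2.96, at 21.1 ± 6.26 against 2.70 ± 2.85 CPM. The list as a whole was called (camera, adjusted p = 6.21e-19, and 0.00137 with an estimated correlation). With GFPtotal 3, 4 and 5 left out, 10 members were higher at a median of 2.48, Gucy1a1 differed by 4.12, and Kcnj8 was not called (log2 fold change 4.21, adjusted p = 0.106). Single GFPlow libraries set the size of several differences: Kcnj8 differed by 8.62 without GFPlow 6, Abcc9 by 8.49 without GFPlow 5 and Notch3 by 3.70 without GFPlow 1, and the list median was 4.08 without GFPlow 3.

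Contractile genes were higher as well, with 8 of 18 smooth muscle members higher and 0 lower (14 and 0 adjusted over the list alone) and a median of 1.75. Acta2, smooth muscle actin, stood at 57.0 ± 22.3 against 1.75 ± 1.72 CPM (log2 fold change 5.00, SE 0.52, adjusted p = 4.43e-05). The smooth muscle myosin heavy chain gene Myh11 differed by 5.41, Actg2 by 5.96 and the transcriptional coactivator Myocd by 5.23. Desmin (Des) and Synpo2 had log2 fold changes of 0.32 and 0.03 and were not called. Ion channel and contractile signalling genes had 7 of 17 members higher and 0 lower (11 and 0 adjusted over the list alone, median 1.58), including the endothelin receptor gene Ednra (2.53, SE 0.30, adjusted p = 0.000148) and the angiotensin receptor gene Agtr1a (3.29). The oxytocin receptor gene Oxtr stood at 859.6 and 1149.7 CPM and was not called. Both lists were called by camera (adjusted p = 2.53e-11 and 1.39e-07), and with an estimated correlation (adjusted p = 0.00964 and 0.00137). When GFPtotal 3, 4 and 5 were left out, 4 contractile and 3 ion channel genes were higher, Myh11 differed by 4.81 and Actg2 by 4.76, and Myocd (adjusted p = 0.126) and Agtr1a (adjusted p = 0.453) were not called. The call on the Agtr1a log2 fold change was also lost with limma-voom (adjusted p = 0.0814). Without GFPlow 6, Myocd differed by 7.18, Myh11 by 6.13 and Acta2 by 5.72, and without GFPlow 4 Actg2 differed by 7.14.

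**Figure D2:**
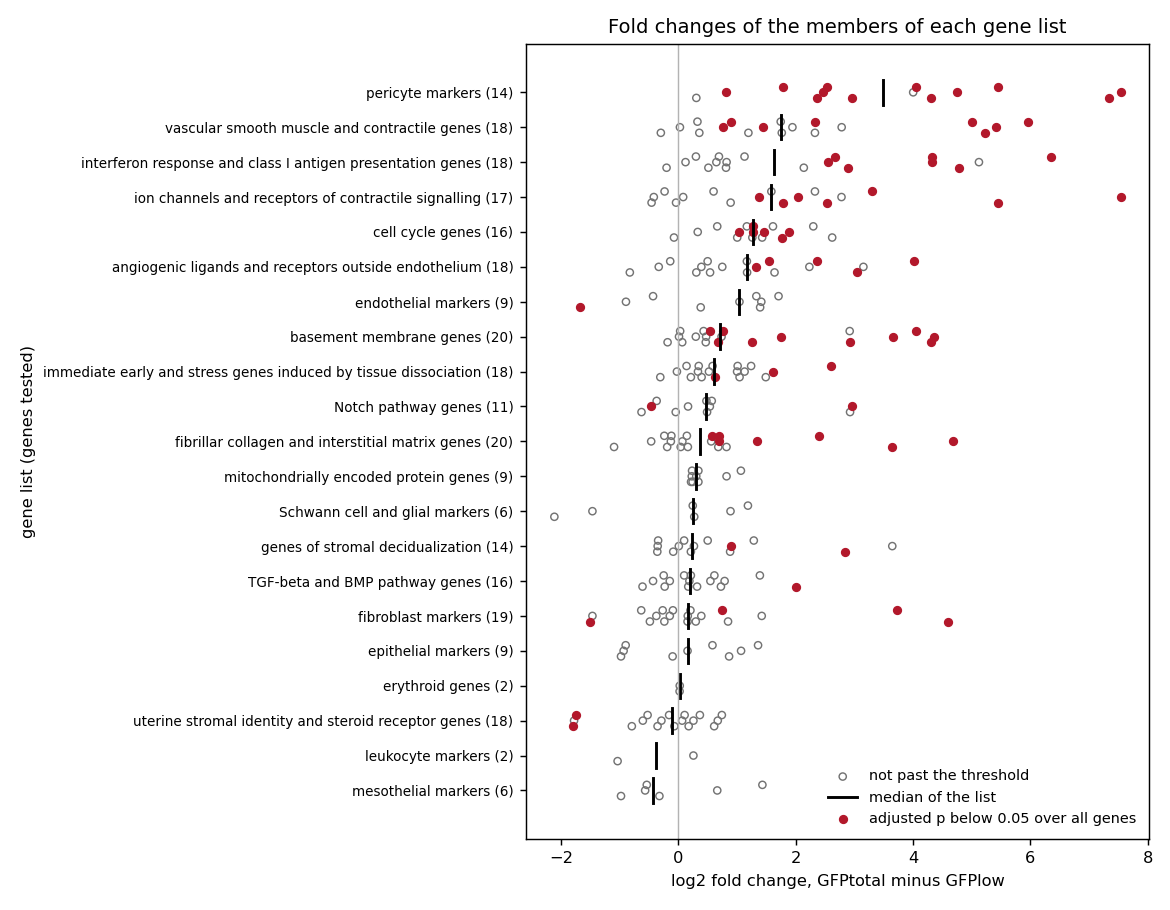
Log2 fold changes, GFPtotal minus GFPlow, of the tested members of each of the 21 gene lists, with a circle per gene (filled where its adjusted p over all genes was below 0.05), a black line for the median and the number tested in brackets. Pericyte markers have the highest median at 3.48, and mesothelial markers the lowest at −0.43.

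Of 20 fibrillar matrix genes, 7 were higher and 0 lower (10 and 0 adjusted over the list alone, median 0.36). The matricellular gene Postn stood at 935 ± 775 against 36.7 ± 16.1 CPM (log2 fold change 4.67, SE 0.69, adjusted p = 0.00233), Col12a1 differed by 3.63 and Col14a1 by 2.40. Col3a1 differed by 0.69, and Col1a1 by 0.82 without passing the test (adjusted p = 0.0689). Of 20 basement membrane genes, 10 were higher and 0 lower (14 and 0 adjusted over the list alone, median 0.70), including the collagen-binding integrin gene Itga1 (4.36, SE 0.44, adjusted p = 2.45e-05), Mcam (4.30) and the laminin gene Lama4 (3.65). Camera called both lists (adjusted p = 0.000796 and 3.56e-09), and neither with an estimated correlation (adjusted p = 0.129 for fibrillar matrix and 0.0603 for basement membrane). In the fit without GFPtotal 3, 4 and 5, 8 fibrillar and 4 basement membrane genes were higher, and Postn differed by 2.75, Col12a1 by 2.65, Lama4 by 2.16 and Mcam by 3.66.

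Fibroblast markers lay on both sides: 3 of 19 were higher and 1 lower (4 and 1 adjusted over the list alone, median 0.16). Camera did not call the list (adjusted p = 0.444). Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0162). The members called higher were Fap (log2 fold change 4.59, SE 0.45, adjusted p = 2.51e-05), a serine protease of activated fibroblasts, the small proteoglycan gene Aspn (3.72) and Col15a1 (0.74). The member called lower was Smoc2 (−1.51). Uterine stromal identity and steroid receptor genes had 0 of 18 members higher and 2 lower (1 and 4 adjusted over the list alone, median −0.11, camera adjusted p = 0.246). Wnt4 (−1.74, SE 0.41, adjusted p = 0.0181) and Gli1 (−1.79, SE 0.47, adjusted p = 0.0349) were lower, and neither was called without GFPtotal 3, 4 and 5 (adjusted p = 0.199 and 0.311). Gli1 also lost its call without GFPtotal 3, 4, 5 or 6 or GFPlow 1, 2 or 3 alone and with limma-voom (log2 fold change −2.14 to −1.37 over all settings). The oestrogen receptor gene Esr1 and the progesterone receptor gene Pgr had log2 fold changes of −0.61 and −0.29 and were not called. Among decidualization genes, 2 of 14 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.112): the cyclooxygenase gene Ptgs2 (2.84, SE 0.52, adjusted p = 0.00354) and Klf9 (0.89). Klf9 was not called without GFPtotal 3, 4 and 5 (adjusted p = 0.438), nor without GFPtotal 3 or 4 or GFPlow 2 alone or with total library size as the only scaling (log2 fold change 0.43 to 0.97 over all settings). Camera called the decidualization list without GFPtotal 3, 4 and 5 (adjusted p = 0.00362), without GFPtotal 3, GFPtotal 5 or GFPlow 6 alone (adjusted p = 0.0373, 0.0303 and 0.0303) and with no low-count filter (adjusted p = 0.0380).

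Genes of signalling to the vessel wall were in part higher. Of 18 angiogenic genes, 5 were higher and 0 lower (8 and 1 adjusted over the list alone, median 1.17), and the list was called (camera, adjusted p = 4.32e-05, and 0.00559 with an estimated correlation). Vegfd differed by 4.01 (SE 0.71, adjusted p = 0.00629), the Tie2 ligand gene Angpt1 by 3.04, Fgf1 by 2.37 and Nrp1 by 1.55, while Vegfa had a log2 fold change of −0.83 and was not called (adjusted p = 0.128). Leaving out GFPtotal 3, 4 and 5 left 3 members higher at a list median of 0.41, with Vegfd at 1.80 and Fgf1 not called (adjusted p = 0.0903). Vegfd was also not called with limma-voom (adjusted p = 0.0766, the highest over all settings) or with the replicate block (adjusted p = 0.0731). Of 11 Notch pathway genes, Notch3 was higher and Notch2 lower (−0.47, SE 0.13, adjusted p = 0.0462), with 2 higher and 1 lower adjusted over the list alone, a median of 0.48 and a camera adjusted p of 0.325. The Notch2 call held without GFPtotal 2 or GFPlow 1 alone and was lost without any other single library, without GFPtotal 3, 4 and 5, and under 4 other settings (log2 fold change −0.54 to −0.42, adjusted p up to 0.229). Of 16 TGF-beta and BMP genes, 1 was higher and 0 lower (2 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.325).

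Cell cycle genes were higher in GFPtotal, with 6 of 16 members higher and 0 lower (10 and 0 adjusted over the list alone, median 1.27; camera adjusted p = 2.29e-08, and 0.0110 with an estimated correlation). The proliferation marker Mki67 stood at 174 ± 28.5 against 63.2 ± 25.2 CPM (log2 fold change 1.46, SE 0.22, adjusted p = 0.000755). Cenpf differed by 1.89, Tpx2 by 1.76 and Top2a by 1.27. With those 3 GFPtotal libraries (3, 4 and 5) left out, 2 members were higher at a median of 1.31, and Tpx2 (adjusted p = 0.165) and Top2a (adjusted p = 0.0664) were not called. Leaving out GFPtotal 3 or 4 alone also ended both calls, GFPlow 2 or 3 that of Tpx2, and GFPtotal 6, GFPlow 1 or 6 or total library size as the only scaling that of Top2a (adjusted p up to 0.0747 for Top2a). Immediate early and stress genes, which tissue dissociation can induce, had 3 of 18 members higher and 0 lower (5 and 0 adjusted over the list alone, median 0.60): Atf3 (2.60, SE 0.69, adjusted p = 0.0425), Zfp36 (1.61) and Egr1 (0.62). Camera called that list (adjusted p = 5.30e-05), and not with an estimated correlation (adjusted p = 0.0964). Of its members, 0 were called by edgeR without GFPtotal 3, 4 and 5, at a median of 0.48. Leaving out GFPtotal 3 or 4 or GFPlow 4 alone ended the calls of both Atf3 and Egr1, GFPtotal 5 or GFPlow 1, 2 or 5 that of Atf3, and GFPlow 3 that of Egr1 (adjusted p up to 0.278 and 0.255). Total library size as the only scaling ended both as well, and the fit with no low-count filter that of Atf3, which differed by 3.36 without GFPlow 6.

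Interferon-response genes were higher in GFPtotal, and most of that difference lay in GFPtotal 3, 4 and 5. Of 18 interferon and class I genes, 7 were higher and 0 lower (11 and 0 adjusted over the list alone, median 1.63). Ifit3 differed by 6.35 (SE 1.35, adjusted p = 0.0190), Ifi44 by 4.78, and Ifit1 by 4.32, at 158 ± 137 against 7.93 ± 4.03 CPM. The class I genes B2m (0.81, adjusted p = 0.0675) and H2-K1 (0.12, adjusted p = 0.815) were not called. Camera called the list (adjusted p = 2.40e-07), and not with an estimated correlation (adjusted p = 0.181). The mean log2 CPM of the list was 5.94 to 6.03 in GFPtotal 3, 4 and 5, 3.69 to 4.25 in GFPtotal 1, 2 and 6, and 2.56 to 3.60 in GFPlow. By limma-voom, 2 of the 18 were called. Without GFPtotal 3, 4 and 5, 3 members were higher and the median was 0.26. Ifit1 was then still called (2.07, adjusted p = 0.0103), and Ifit3 (2.61, adjusted p = 0.237) and Ifi44 (1.29, adjusted p = 0.526) were not. Ifi44 kept its call without GFPtotal 1, 2 or 6 alone and lost it without any other single library. The list median was 1.04 without GFPtotal 3 alone, and Ifit3 differed by 7.01 without GFPlow 1. Summed epithelial markers stood at 51.3 to 133 CPM in GFPtotal 3, 4 and 5, 20.4 to 32.4 CPM in GFPtotal 1, 2 and 6 and 20.2 to 79.6 CPM in GFPlow. For the fibroblast sum these ranges were 6512 to 7597, 10083 to 11020 and 5983 to 9984 CPM, and for the pericyte sum 2020.3 to 2540.2, 1285 to 1684 and 137 to 197 CPM.

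**Figure D3:**
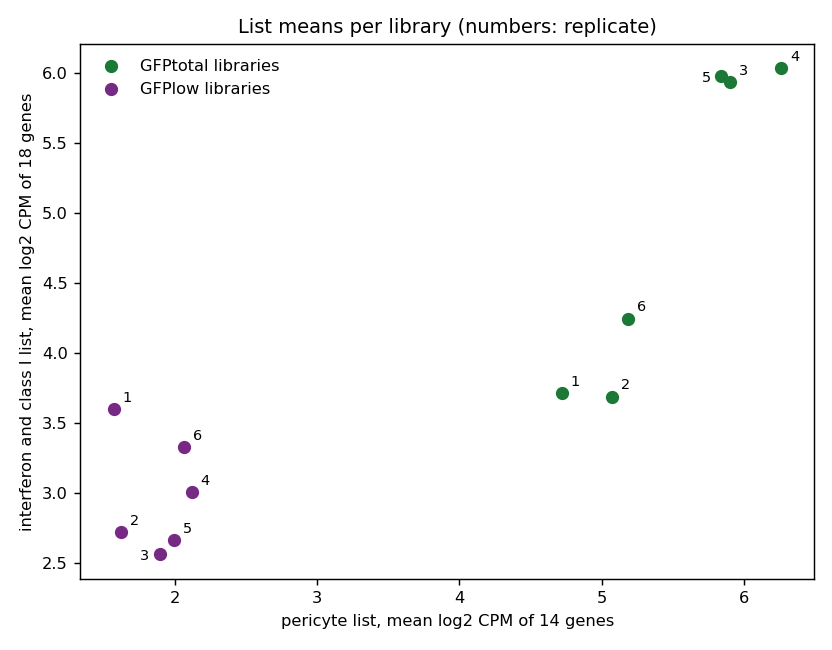
Mean log2 CPM per library of the pericyte list (14 genes, horizontal axis) and of the interferon and class I list (18 genes, vertical axis), with a dot per library, numbered by replicate, in green for GFPtotal and purple for GFPlow. GFPtotal 3, 4 and 5 lie at 5.94 to 6.03 on the vertical axis, and GFPtotal 1, 2 and 6 at 3.69 to 4.25.

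The largest differences outside the lists included the neighbouring olfactory receptor genes Olfr78 and Olfr558 on chromosome 7. Olfr78 had 1292 counts in GFPtotal and 3 in GFPlow, a ratio of CPM of 518.5 with a 95% counting interval of 177 to 2518 (adjusted p = 1.70e-06). All 3 of those counts lay in GFPlow 6. With that library left out the GFPlow count was 0. An assumed floor of 3 counts over the other 5 GFPlow libraries then gave a ratio of CPM of 421.6, which is not a lower bound from the data. Olfr558 differed by 7.98 on the log2 scale (SE 0.59, adjusted p = 7.88e-07). The cationic amino acid transporter gene Slc7a2 had the smallest p-value, at 211 ± 40.4 against 1.92 ± 1.02 CPM (log2 fold change 6.77, SE 0.34, adjusted p = 7.48e-09), followed by Btbd3 (2.75, adjusted p = 2.98e-07). Map3k7cl differed by 5.94, the matrix proteoglycan gene Prelp by 5.47 and Ccn3 by 4.93. In the fit that left out GFPtotal 3, 4 and 5, Prelp differed by 3.80 and Ccn3 by 2.31. With limma-voom Ccn3 was not called (adjusted p = 0.112).

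Among the genes lower in GFPtotal, the calcium channel gene Cacna1e had a log2 fold change of −2.93 (SE 0.53, adjusted p = 0.00521), the noradrenaline transporter gene Slc6a2 −2.43 and Nos1 −2.35 (SE 0.37, adjusted p = 0.00116). Without GFPlow 1, the log2 fold changes of Cacna1e and Slc6a2 were −2.20 and −1.71. Klhl32 stood at 10.9 ± 8.46 against 55.2 ± 17.5 CPM (−2.34, adjusted p = 0.0104). The netrin receptor gene Unc5c, the decoy receptor gene Il13ra2 and the immune checkpoint ligand gene Cd200 had log2 fold changes of −1.75, −1.67 and −1.60. The abundant giant protein gene Ahnak stood at 706 ± 111 against 1279 ± 169.96 CPM (−0.86, SE 0.14, adjusted p = 0.00161). Rasgrf1, Arl4c and Micall1 had log2 fold changes of −1.33, −1.48 and −1.59, the last with exons that overlap an antisense gene. Slc6a2, Unc5c and Il13ra2 were not called without GFPtotal 3, 4 and 5 (adjusted p = 0.209, 0.0940 and 0.149), and Klhl32 and Arl4c then had log2 fold changes of −1.67 and −0.85. Single libraries also ended calls: GFPtotal 2, 3 or 5 or GFPlow 2 or 3 that of Slc6a2, GFPtotal 1 or 3 or GFPlow 2, 4, 5 or 6 that of Unc5c, and GFPtotal 4 or 5 or GFPlow 2, 3 or 6 that of Arl4c (adjusted p up to 0.0766 for Arl4c). The fit with no low-count filter ended the calls of all 3, and limma-voom that of Slc6a2.

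Markers of other cell types gave few calls. Of 9 endothelial markers, edgeR called 0 higher and 1 lower (1 and 1 adjusted over the list alone, 3 and 1 at an unadjusted p below 0.05; median 1.04, camera adjusted p = 0.444), and limma-voom 1 and 0. DESeq2, which tested 15 endothelial markers, called 3 higher and 1 lower. The gene that edgeR called lower was the vascular cadherin gene Cdh5 (−1.67, SE 0.45, adjusted p = 0.0374). Cdh5 was not called without GFPtotal 3, 4 and 5 (adjusted p = 0.273), nor without GFPtotal 3, 4, 5 or 6 or GFPlow 1 or 3 alone or with limma-voom. Of 9 epithelial, 6 mesothelial and 6 Schwann cell and glial markers, 0 were called by edgeR in either direction, adjusted over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there were 0 epithelial genes, 1 mesothelial gene lower and 2 glial genes lower, and limma-voom called 0 of each. DESeq2, which tested 13 epithelial, 7 mesothelial and 8 glial markers, called 0, 0 and 3 (the 3 lower). Over the genes tested by edgeR, the medians of these lists were 0.16, −0.43 and 0.26 and their camera adjusted p-values 0.727, 0.405 and 0.538. By mean log2 CPM, the most abundant tested members were Muc1 (0.58) and Prom1 (−0.10) of the epithelium, Igfbp5 (−0.32) and Wt1 (−0.54, and −0.93 with an adjusted p of 0.0106 without GFPtotal 3, 4 and 5) of the mesothelium, and Ngfr (−1.47) and Mbp (1.18) of glia. By mean CPM, Lcn2 (1.36, at 17.2 and 6.73 CPM) exceeded Muc1, and Gap43 (−2.11, adjusted p = 0.102, at 1.34 and 5.79 CPM) exceeded Mbp. Camera's direction was lower for epithelium, against its median and its mean of 0.12, and lower for glia, where the median was 0.26 and the mean −0.17. The 2 tested leukocyte genes (Cd68 at 0.26 and Itgam at −1.04) and the 2 erythroid ones (Alas2 and Bpgm, both at 0.02) were not called by edgeR, 0 of them adjusted over the list alone, at an unadjusted p below 0.05 or by limma-voom, and these lists were too short for camera. DESeq2 tested 8 leukocyte and 2 erythroid genes and called 0. Summed over its 20 genes, the leukocyte list stood at 10.2 ± 5.08 CPM in GFPtotal and 10.8 ± 4.97 CPM in GFPlow (exact two-sided permutation p = 0.855, n = 6 each; adjusted p = 0.926 over 8 lists). The Schwann cell and glial sum over 15 genes was 121 ± 90.5 against 318 ± 111 CPM (exact two-sided permutation p = 0.0130, n = 6 each; adjusted p = 0.0519) and consisted mostly of 1 gene, Ngfr, which is also in the fibroblast list and had means of 111 and 306 CPM. The other 14 genes summed to 10.6 ± 5.09 against 11.9 ± 7.13 CPM (exact permutation p = 0.721, n = 6 each). Of the other sums, that of the pericyte list differed (ratio 11.3, exact permutation p = 0.00216, adjusted p = 0.0173), and those of epithelium, endothelium, erythroid cells and fibroblasts had ratios of 1.33, 1.02, 0.984 and 1.10 and that of mesothelium means of 503 and 607 CPM (exact permutation p from 0.132 to 0.926). The endothelial ratio does not show that endothelial transcripts were level, because its members lay on both sides. Eng and Kdr stood at 17.9 and 11.2 CPM in GFPtotal against 24.1 and 20.8 CPM in GFPlow. Emcn and Tek stood at 14.3 and 11.4 CPM against 4.39 and 5.53 CPM. These genes were not called by edgeR.

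Mitochondrially encoded protein genes had 0 of 9 members called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p below 0.05 and 0 by DESeq2 or limma-voom; median 0.30, camera adjusted p = 0.325), and mt-Co1 and mt-Nd5 had log2 fold changes of 0.24 and 0.34. The mitochondrial share of the counts was 41.1% ± 6.87 in GFPtotal and 40.05% ± 4.21 in GFPlow (SD, n = 6 each), with the 2 lowest shares, 32.4% and 33.6%, in GFPtotal 4 and 5. Without GFPtotal 3, 4 and 5, 2 of the 9 genes were called higher and the median was 0.78. Camera at the preset correlation then called the list (adjusted p = 1.69e-07), as it did without GFPtotal 5 alone (adjusted p = 0.0343). Over all libraries the estimated correlation of this list was 0.830, far above the preset one, and the camera adjusted p with it was 0.698. That test is not given for the fits with libraries left out, so whether these calls would hold stays open.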

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

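The tests of the interferon genes, of the name in a file header and of the excess of higher genes were chosen after those results had been seen. The search for single libraries far from the rest of their group was planned.

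Within 1 group, 7 of 162 sets of 6 library values had their highest or lowest value apart from the others by more than Dixon's 95% limit, where chance gives about 1 in 20, or 8.1. In log2 CPM, GFPlow 6 was high for Olfr78 (−1.76, the other GFPlow libraries at −2.91) and for Kcnj8 (0.77, others −2.91 to −1.84). GFPlow 1 was low for Agtr1a (−2.91, others −0.52 to 0.45). GFPtotal 4 was high for Notch3 (5.07, others 4.05 to 4.41) and for Cd68 (4.09, others 1.92 to 2.65). GFPtotal 5 was low for Top2a (4.34, others 5.24 to 5.73), and GFPtotal 3 was low for Rhou (5.08, others 5.59 to 5.86).

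Interferon genes were higher in GFPtotal 3, 4 and 5 (mean log2 CPM 5.94 to 6.03) than in GFPtotal 1, 2 and 6 (3.69 to 4.25), which in turn lay above the GFPlow libraries (2.56 to 3.60). Leukocytes among the sorted cells are argued against as the source of these transcripts, since they would bring their own: over the 6 GFPtotal libraries the summed CPM of 20 leukocyte markers ranged over 13.0 (11.2, 20.1 and 7.12 in GFPtotal 3, 4 and 5, and 7.12 to 8.04 in the others) and that of the interferon list (20 genes, tested or not) over 2954, a ratio of 0.00438. A larger share of GFP-high cells in those 3 libraries is argued against as the whole cause, since it would raise transcripts nearly restricted to these cells by 1 common factor: the mean log2 CPM of the 10 called genes outside the interferon list that were at least 32-fold higher in GFPtotal, at 5 or more there, ranged over 1.06 within GFPtotal and that of the interferon list over 2.34, a ratio of 2.21, and 8 of the 10 ranged over less than the interferon list (Rgs5 over 0.65 and Map3k7cl over 0.42). Prelp (3.09) and Dkk2 (3.22) ranged over more, and both were highest in GFPtotal 3, 4 and 5. The 10 genes were picked by a called difference in the same libraries, which favours genes with little spread and weakens the comparison. The ranges of single genes are also set against that of a list mean. A part stays open, because the mean of those 10 genes (6.996 to 7.295 against 6.24 to 6.47) and the pericyte list (5.84 to 6.26 against 4.72 to 5.18, a ratio of ranges of 1.52) were higher in the same libraries. The stage of the oestrous cycle is not labelled, so no biological explanation was tested.

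The count file of GFPlow 6 carries a column name of the GFPtotal series, N8, where the other GFPlow files carry S1 to S5. A library of GFPtotal cells is argued against by its pericyte genes: their mean log2 CPM was 2.06 in GFPlow 6, 2.66 below the lowest GFPtotal library (4.72), and within the other GFPlow libraries (1.57 to 2.12). Its smooth muscle list, at 2.81, and Rgs5, at 3.47, stood above the other GFPlow libraries (1.91 to 2.37 and 0.053 to 2.97) and below every GFPtotal library (lowest 4.06 and 9.21), so a small share of such cells is not excluded. Where the name came from was not tested, and leaving GFPlow 6 out gave 610 genes changed.

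More genes were higher than lower in GFPtotal (661 against 124). The choice among the 5 scalings tried is argued against as the whole cause, since the lowest share of higher calls was 66.3%, with total library size only. That share was 84.2% with TMM. The other scalings rest on a similar assumption, that most genes do not differ, so their closeness to TMM adds little. A candidate explanation is that GFPlow cells, which GFPtotal contains, limit how far a transcript can fall: 15.3% of the lower calls (19) and 51.3% of the higher calls (339) reached 4-fold (Fisher's exact p = 1.59e-14 across genes, which are not independent replicates). The largest fall, −5.04 on the log2 scale, would by dilution alone need 97.0% of the GFPtotal cells to lack the transcript. The comparison of fold sizes does not test the numbers of genes higher and lower. The composition of the sorted cells was not measured either, so this explanation stays a hypothesis.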

How the results depend on the processing

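The fits without GFPtotal 3, 4 and 5 and without mitochondrial genes were chosen after the results had been seen. Of 64 named genes past the threshold, 40 kept their direction and call under every setting, and 24 lost the call under at least 1. Of 9 lists past it, 5 kept their call under every setting. The values that changed sign (28 of named genes and 11 of lists) belonged to genes and lists that were not called. The cause of the changes below was not tested, except that fits without libraries have fewer samples.

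With DESeq2, the number of genes changed was 1787 against 785 (genes higher in GFPtotal, 1339, and genes lower in GFPtotal, 448), with genes higher at least 2-fold in GFPtotal at 1190 and genes lower at least 2-fold in GFPtotal at 280. All 785 genes were among them, in the same direction. With GFPtotal 3, 4 and 5 left out, these 5 counts were 295, 245, 50, 210 and 26. With total library size only, genes lower in GFPtotal were 257 and genes lower at least 2-fold in GFPtotal 145. When each library was left out in turn, genes changed ranged from 467 to 970, genes higher in GFPtotal from 406 to 791, genes lower in GFPtotal from 61 to 179, genes higher at least 2-fold in GFPtotal from 368 to 704, and genes lower at least 2-fold in GFPtotal from 42 to 114. The lowest of each came without GFPtotal 3. Genes lower in GFPtotal also dropped by over 1.5 times without GFPtotal 4 (71), GFPtotal 5 (69), GFPlow 2 (67), GFPlow 3 (64) and GFPlow 6 (70). The other settings gave 582 to 865 genes. The count of fixed gene lists past the threshold was 5 with an estimated correlation and 9 to 12 elsewhere. DESeq2 and limma-voom gave no list tests, and the camera fits with libraries or the filter changed used the preset correlation. Lists not called in the report that gained a call were decidualization (4 camera settings with libraries or the filter changed, GFPtotal 3, 4 and 5 left out, and fry), endothelium with no low-count filter (adjusted p = 0.0380), mitochondrially encoded genes without GFPtotal 5 or GFPtotal 3, 4 and 5, and fibroblast and Notch by fry, which does not compare a list with other genes (adjusted p = 0.0162 and 0.00112). With limma-voom, the log2 values of Abcc9 (8.29), Kcnj8 (7.20), Myh11 (6.50), Myocd (6.30) and Atf3 (3.46) were larger and those of Ifit3 (5.65), Ccn3 (3.83), Ifit1 (3.64), Ifi44 (3.58) and Vegfd (3.09) smaller by over 1.5-fold.

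The Pdgfrb log2 fold change was 0.79 with total library size only (adjusted p = 0.0814), 0.68 with limma-voom (adjusted p = 0.0516), 0.64 without GFPtotal 3, 4 and 5 (adjusted p = 0.207) and 0.66 to 0.91 with each library left out in turn.

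Signs changed as follows. The Alas2 log2 fold change was −0.00072 with RLE factors, −0.074 with total library size only, −0.0019 with DESeq2, −0.0066 without mitochondrial genes and −0.11 to 0.15 with each library left out. The Bpgm log2 fold change was −0.20 with total library size only, −0.0062 without mitochondrial genes and −0.28 to 0.39 with each library left out. The Prom1 log2 fold change was 0.0074 with total library size only, 0.20 with limma-voom and −0.60 to 0.28 with each library left out. The Itgam log2 fold change was 0.73 with limma-voom, 0.059 with the replicate block and −1.31 to 0.086 with each library left out. The Cd68 log2 fold change was −0.53 without GFPtotal 3, 4 and 5 and −0.27 to 0.64 with each library left out. The list epithelium median log2 fold change was −0.012 with no low-count filter, −0.14 with the replicate block, −1.03 without GFPtotal 3, 4 and 5 and −0.10 to 0.38 with each library left out. The list mesothelium median log2 fold change was 0.65 with no low-count filter. The list fibroblast median log2 fold change was −0.054 and the list schwann_glia median log2 fold change −0.70 without GFPtotal 3, 4 and 5, the latter −0.089 to 0.38 with each library left out. The list uterine_stroma_identity median log2 fold change ranged from −0.22 to 0.055 with each library left out.

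The replicate block gave 582 genes changed, 520 of them shared with the fit without it. It ended the calls of 9 named genes: Atf3, Cdh5, Egr1, Ifi44, Ifit2, Ifit3, Il13ra2, Notch2 and Vegfd. Same-numbered libraries deviated from their group means with correlations of −0.139 to 0.0892, 0 of them above 0.1. Of 6 GFPtotal libraries, 2 correlated best with their own number. Deviations within GFPtotal also carry the split of these libraries on the first principal component. The check therefore does not decide whether the numbers pair the libraries. Depth and spread limit what could be called: 16.5% of simulated 2-fold rises were recovered.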

Other observations

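The split of the libraries for the gene counts was planned, and its repeat for lists with an estimated correlation was chosen after the result with the preset correlation had been seen. The low-count genes were chosen after their values had been seen.

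Several list members had too few counts for the test but were unevenly spread, given here as summed counts over 6 GFPtotal and 6 GFPlow libraries. The prostaglandin receptor gene Ptger3 had 239 and 0, with 151 in 1 library. The pericyte-list genes Rasl12, Vtn, Cox4i2 and Higd1b had 190 and 2, 94 and 1, 42 and 0, and 32 and 0, with 105, 33, 19 and 17 in 1 library. Fkbp5, of the decidualization list, had 274 and 3, with 129 in 1 library. The endothelial-list genes Esam, Vwf, Ecscr and Pecam1 had 144 and 14, 130 and 24, 96 and 8, and 66 and 17. Up to 40, 59, 43 and 17 of these counts lay in 1 library. The opposite was seen for the BMP receptor gene Bmpr1b (6 and 101, with 37 in 1 library) and the glial receptor gene Gfra3 (4 and 103, with 51 in 1 library). It was also seen for the endothelial-list genes Mmrn2 (2 and 33, with 16 in 1 library) and Egfl7 (9 and 18). Among mitochondrially encoded genes, mt-Co2 had 3 and 11 counts, mt-Co3 3 and 0, mt-Atp6 10 and 13, and mt-Atp8 0 and 0, where mt-Co1 stood at 20908 and 17687 CPM. Whether the mapping quality filter removed reads of these 4 genes, as it does where near-identical nuclear copies exist, was not tested, so the counts are not measures of their expression.

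The reporter is carried on a genomic clone around Pdgfrb. Of the protein-coding genes within 200 kb, 5 were tested by edgeR (Tcof1, Arsi, Camk2a, Hmgxb3 and Slc26a2), with adjusted p from 0.240 to 0.897. Slc26a2 stood at 57.0 and 53.5 CPM in GFPtotal and GFPlow. Slc6a7, Cdx1, Csf1r and Pde6a had too few counts for the test.

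Of 100 splits of the 12 libraries into groups of 6, drawn from the 462 possible with the real one included, 1 split (the real one) gave as many genes changed: 785, against 15 in the highest other. The same held for genes higher (1 split, 661 against 12), genes lower (1 split, 124 against 3), genes higher at least 2-fold (1 split, 575 against 12) and genes lower at least 2-fold (1 split, 78 against 3), so chance can be excluded for these counts. For the number of lists called with the preset correlation, 11 splits gave as many as the real 9, with 12 in the highest other. Those other splits kept 4 or 5 of the 6 libraries of a group together, and so part of the real difference. Splits that kept only 3 together gave at most 4 lists. The comparison therefore does not decide whether chance can be excluded for that count. With an estimated correlation, 1 split (the real one) gave 5 lists and the highest other 0. This repeat was chosen after the planned count had been seen. Other splits also leave the real difference within their groups, where it can raise the estimated correlation of the shifted lists. The repeat therefore does not decide whether chance can be excluded for the number of lists.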
